A study of Mus musculus with 19 samples.

How the data were processed

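The series holds 19 samples of mouse cells: 5 RNA-seq libraries, 8 ChIP-seq libraries including 1 input, and 6 DamID-seq libraries. DamID marks the sites where a protein fused to a bacterial DNA methylase has been close to DNA. Most samples came from embryonic stem cells (ESC) of the E14 line, grown on irradiated mouse embryonic fibroblasts per the labels. The others came from neural progenitors (NeuP), which were derived through embryoid bodies, Noggin and growth in FGF2 and EGF, and for which the labels name no line. The growth protocol names the ESC lines E14, 16.7 and D3, and whether NeuP came from the line of the ESC libraries is not given in the sources used here. Nup153, a nucleoporin of the nuclear basket of the pore, was knocked down in ESC with 1 of 2 lentiviral hairpins, called #2 and #4 in the labels, and a non-target hairpin was the control. Per the labels, transduced cells were selected with puromycin for at least 4 days.

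The RNA values were deposited as FPKM, fragment counts scaled to transcript length and library depth, in a table of 24016 transcripts with 1 transcript per gene symbol. Per the labels the authors sorted reads with CASAVA 1.8.2, aligned RNA reads with STAR 2.2.0c and other reads with Bowtie2 2.1.0 to the mm9 build, used HOMER 4.6, and compared RNA with edgeR, for which no version is given. The labels also say that the RNA libraries were strand-specific and made from polyadenylated RNA. The peaks were deposited as 9 lists of start and end positions, 7 from ChIP and 2 from DamID, with no peak height. Per the file headers the ChIP lists came from HOMER findPeaks, in the factor style with a fixed width for Oct4 and in the histone style for Ring1B and Cbx7, against an IgG library from ESC, which was used for the NeuP list too. Each ChIP list came from 1 library. Each DamID list stood for 2 replicates, and the files do not say how these and the GFP control were combined.

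Low FPKM values were whole multiples of 1 read per library once multiplied by transcript length, so the depth of each RNA library was recovered from the size of that step. Between 99.1% and 99.7% of the low values tested came out whole within 0.1 of a read. The depth was 25.4 M fragments in the control library, 31.2 and 25.5 M in hairpins #2 and #4, and 32.2 and 24.3 M in the NeuP replicates. These depths rest on the table itself, and read totals in the sequencing files may be larger.

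Differential expression was tested with limma 3.58.1 in R 4.3.3, as limma-trend on log2(FPKM + 1), for the 13750 genes with an FPKM of at least 1 in at least 1 library. All 5 libraries entered 1 fit with 3 groups, the knockdown (2 hairpins), the control (1 library) and NeuP (2 replicates). The single control library had no replicate and was assumed to vary like the other groups, and the 2 hairpins were taken as replicates of the knockdown. The labels do not say whether the libraries came from separate cultures, so each p-value measures only the spread between these samples. P-values were adjusted by Benjamini-Hochberg and genes were called at an adjusted p under 0.05, in tests that were all two-sided. The fit had 2 residual degrees of freedom, to which limma's moderation added 1.74. Because the table was made from whole reads, voom on the recovered reads was run as well.

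Groups of genes were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the genes of a list with all other genes, whereas fry, run beside it, tests whether the genes of a list move on balance one way. Camera was also run with the correlation estimated from the data. In that form its p-value rests on the 2 residual degrees of freedom, so it can hardly call any list. Of 23 lists fixed before the data were examined, 21 were tested: pluripotency, formative and primed epiblast, 2-cell-like, neural progenitor, neuron, glia, mesoderm, endoderm, trophoblast, HOX, subunits of PRC1 and of PRC2, other nucleoporins, feeder fibroblast, p53 targets, interferon response, integrated stress response, proliferation, ribosomal protein, histone and imprinted genes. The other 2 were the targeted gene itself, given as a single gene, and mitochondrially encoded genes, of which 0 matched the table.

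Peaks were compared with bedtools 2.31.1 rules in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), counting a peak as overlapped when it shared at least 1 bp with a peak of the other list. Shares carry Wilson 95% intervals, which cover counting error only. Overlaps given with a fold were set against 1000 circular shifts of the peaks within chromosomes, which gives a one-sided permutation p no smaller than 0.001. Transcript starts of the deposited table, in mm9, placed peaks within 2 kb of a transcription start site (TSS). The median change of the genes in a peak class was ranked among the medians of 10000 random lists of the same size, drawn in 20 bins of mean expression. Figures were drawn with matplotlib 3.10.9.

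The comparisons, their tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Nup153, the 10 genes with the largest change in each direction among those past the threshold, and up to 4 members of each list with the largest change, past the threshold where any passed. Where fewer than 10 genes passed, the places were filled by the smaller of the changes in the 2 hairpins or replicates, and unnamed loci were skipped. A few genes that the rule names are not reported here. For peaks it names list members per class and the 5 widest peaks per list. Both RNA comparisons share the control library, so correlations between changes were set against 200 simulations of unchanged libraries sharing 1 control. The simulated noise was smoothed over expression level. It came from the spread of the hairpin pair for the ESC libraries and of the NeuP pair for NeuP. Genes are not independent replicates, and no p-value was given for such correlations.

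Of the other settings tried, 66 were fixed before the data were examined and 15 were added after the data were seen. The tests were also tested on simulated data in which 50 genes per size had been changed. For the knockdown the fit recovered 0% of genes at 2-fold, 32% at 4-fold, 90% at 8-fold and 90% at 16-fold, with 4 false calls among 13750 genes. For NeuP it recovered 0%, 44%, 72% and 94%, with 5 false calls. The simulated noise of every library came from the pooled fit, in which the NeuP pair had a wider spread than the hairpins. In this pooled fit the comparison of 2 hairpins with 1 control therefore could not call a 2-fold change. A fit of the ESC libraries alone was not simulated. The read sequences and the input library were not used.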

Results

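The data cover RNA, chromatin binding and DNA contact in mouse ESC and in neural progenitors. RNA-seq was done on 1 control ESC library, 2 Nup153 knockdown ESC libraries (hairpins #2 and #4, called below the knockdown) and 2 NeuP libraries. ChIP-seq peak lists were given for the pluripotency factor Oct4 in control and hairpin #2 ESC, for Ring1B in control, hairpin #2, hairpin #4 and NeuP cells, and for Cbx7 in control ESC. Ring1B and Cbx7 are subunits of Polycomb repressive complex 1 (PRC1), which keeps developmental genes silent. DamID peak lists were given for Nup153 and for Oct4. The RNA depth ran from 24.3 to 32.2 M fragments per library. The ChIP libraries held 4.99 M tags for Ring1B in control ESC, 30.8 M and 9.95 M for Ring1B in hairpins #2 and #4, 33.2 M for Ring1B in NeuP, 24.6 and 20.1 M for Oct4 in control and hairpin #2, and 22.5 M for Cbx7. Only Ring1B in the knockdown had more than 1 ChIP peak list, 1 per hairpin, and the control RNA had no replicate, so no error between replicates is given for the other lists or for the control.

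The first comparison asked which genes respond to loss of Nup153 in ESC. Nup153 itself (NM_175749, chromosome 13, 46775271 to 46823218, minus strand, mm9) was measured at 39.4 FPKM in the control library, 20.9 in hairpin #2 and 17.4 in hairpin #4. It was measured at 12.8 and 29.1 FPKM in the NeuP replicates. The change in the knockdown was -1.01 ± 0.55 on the log2 scale (SE, adjusted p = 0.897, limma, Benjamini-Hochberg), with -0.88 and -1.14 in the separate hairpins. The remaining transcript was therefore about 2-fold below the control in both hairpins, although the single gene did not pass the test across all genes.

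**Figure D1:**
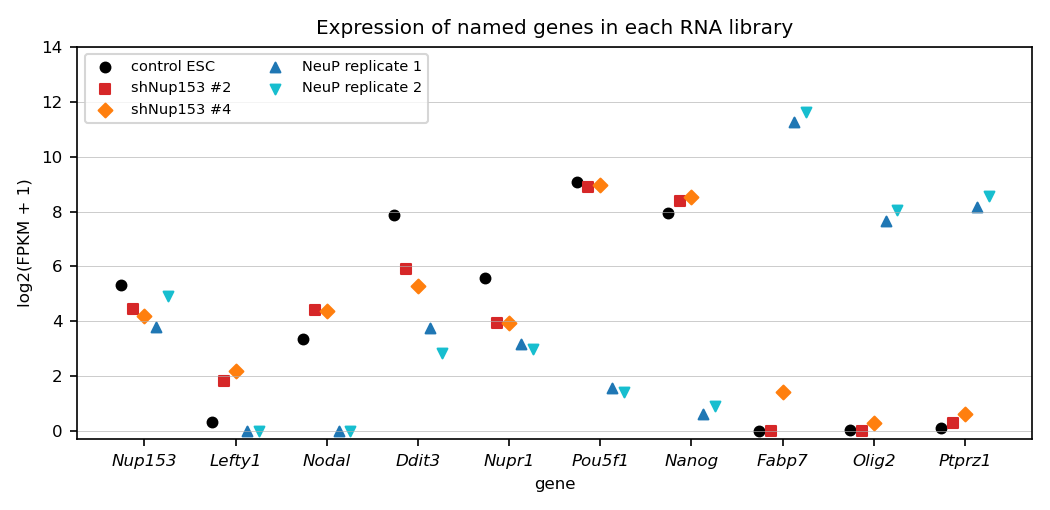
FPKM on the log2(FPKM + 1) scale for Nup153, Lefty1, Nodal, Ddit3, Nupr1, Pou5f1, Nanog, Fabp7, Olig2 and Ptprz1 in each of the 5 RNA libraries, 1 point per library. Nup153 lay at 39.4 FPKM in the control and at 20.9 and 17.4 FPKM in the hairpins, and Pou5f1 lay at 543 FPKM in the control and at a mean of 1.82 FPKM in NeuP.

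Among genes higher in both hairpins by size, the largest change was in Lefty1, a secreted inhibitor of Nodal signalling, at 0.247 FPKM in the control and 2.53 and 3.56 FPKM in hairpins #2 and #4 (log2 change 1.69 ± 0.21, SE). Ppp1r10, a regulatory subunit of protein phosphatase 1 in the nucleus, stood at 3.74 FPKM in the control and 12.2 ± 0.502 (SD, n = 2) in the knockdown, and Pcf11, which acts in cleavage of RNA 3' ends, at 7.82 and 21.3 ± 2.03. Fam208a, a subunit of the HUSH silencing complex, had a log2 change of 1.37 ± 0.64 and the imprinted zinc finger gene Peg3 one of 1.22 ± 0.18. The Notch receptor gene Notch3 was at 10.7 FPKM in the control and 26.3 ± 0.353 in the knockdown. The F-box gene Fbxo36 had a log2 change of 1.41, the coagulation cofactor gene Pros1 1.28 and the peroxisomal and mitochondrial membrane gene Mpv17l 1.17.

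Among genes lower in both hairpins by size, Ddit3, the stress transcription factor CHOP, was at 233 FPKM in the control and 48.4 ± 14.7 in the knockdown (log2 change -2.28 ± 0.52, SE). Nupr1, another stress-induced chromatin protein, was at 46.3 FPKM and 14.4 ± 0.0163. The muscle-type genes Cox6a2 and Myl3 had log2 changes of -1.99 and -1.68, and the keratin gene Krt17 -1.55. Sohlh1, a germ-cell transcription factor, was at 4.26 FPKM in the control and 1.13 and 0.768 FPKM in the hairpins. The circadian repressor gene Ciart had -1.27, the polarity gene Crb3 -1.18, the zinc finger repressor gene Zbtb32 -1.18 and Derl3, which acts in degradation of misfolded proteins of the endoplasmic reticulum, -1.08. These genes were named by size, and each had an adjusted p of 0.825 in limma (Benjamini-Hochberg), as had the genes higher by size except Fam208a (0.858) and Mpv17l (0.891).

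No gene passed the test in the knockdown. Limma called 0 of 13750 genes after Benjamini-Hochberg adjustment, 814 genes had an unadjusted p under 0.05 (617 higher, 197 lower), and voom on the recovered reads called 0 with 482 at that unadjusted level. With the 3 ESC libraries alone limma also called 0, but 4673 genes (3334 higher, 1339 lower) had an unadjusted p under 0.05 and the smallest adjusted p was 0.0822. Without NeuP replicate 1 or 2 such genes numbered 4680 and 4668, with 0 called. Without a filter on low values the same fit called 55 higher and 175 lower of 24016 genes. The rows this adds stayed under 1 FPKM in every library, and 4618 rows were at 0 in all 5 libraries. Those calls thus rest on a spread estimated with rows at or near 0. By size, 42 genes were at least 2-fold higher in both hairpins, 22 were at least 2-fold lower and 0 went opposite ways. Simulated unchanged libraries sharing 1 control gave a mean of 0.005 for each direction. The simulated control varied only by the smoothed spread between the hairpins. An outlying control value of a single gene, which would move both hairpins alike, is not covered by it. After quantile normalization the split turned to 23 higher and 45 lower, and the median change over all genes moved from 0.08 to 0.00. With a pseudocount of 0.1 the counts were 388 and 65, and with a pseudocount of 5 they were 1 and 4.

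The changes in the 2 hairpins ran together across genes, with a Pearson r of 0.856 and a covariance of 0.0960, and 85.1% of genes had the same sign. Sharing 1 control library alone gave a simulated r of 0.501 (SD 0.00748), a covariance of 0.0166 and 66.7% of the same sign. Genes are not independent replicates, and an error of the single control library would enter both hairpins alike. The median SD between the hairpins was 0.06 log2 units, and 48 genes differed 2-fold between them. In the NeuP pair it was 0.29 log2 units with 2220 such genes, and this wider spread entered the pooled test of the knockdown.

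Fixed lists asked which groups of genes moved in the knockdown, and 7 of the 21 were called by camera with its preset correlation. None was called with an estimated correlation or with fry, and 0 members of any list passed the threshold across all genes.

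Genes of the 2-cell-like state, a rare state of ESC that expresses transcripts of the early embryo, were higher as a list (median 0.66, 16 genes, camera adjusted p = 5.9e-07, limma). The list had an adjusted p = 0.759 with an estimated correlation. Zscan4d had a log2 change of 1.16, Usp17lb 1.16, Usp17la 1.09 and Zscan4c 0.72, and 6 of the 16 genes were higher adjusted over the list alone, all from the near-identical Zscan4 and Usp17 families. Genes of endoderm, the lineage that forms gut and extraembryonic yolk sac layers, were higher as well (median 0.60, 17 genes, adjusted p = 3.7e-06, and adjusted p = 0.758 with an estimated correlation). Cubn, an endocytic receptor of visceral endoderm, had 1.03, Sox17 0.82, Gata4 0.69 and Dab2 0.69, the last with 0.39 and 0.99 in the separate hairpins.

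Pluripotency genes were also higher as a list (median 0.33, 27 genes, camera adjusted p = 0.0114, limma, and adjusted p = 0.758 with an estimated correlation). The members with the largest changes were the TGF-beta family ligand Gdf3 (1.08), Dppa2 (0.79), Nr0b1 (0.77) and Mycn (0.59). Formative and primed epiblast genes, which mark the step after the naive state, had a median of 0.30 over 8 genes (adjusted p = 0.0285, and adjusted p = 0.732 with an estimated correlation). Nodal, the signal that Lefty1 inhibits, had 1.05, the homeobox gene Otx2 0.52 and Zic2 0.36 (0.51 and 0.20 in the hairpins), and 1 gene, Nodal, was higher adjusted over the list alone. After quantile normalization the formative list was not called (adjusted p = 0.0904), and with a pseudocount of 0.1 neither pluripotency (0.156) nor the formative list (0.0897) was called. With voom both ended as well (0.0854 each), and with the length trend removed the formative list ended (0.0795). Pluripotency was not called without hairpin #4 (0.0620), and the formative list not without hairpin #2 (0.122). With a pseudocount of 5, which shrinks changes of weakly expressed genes, the medians were 0.31 for the 2-cell-like, 0.32 for the endoderm and 0.15 for the formative list, and without a filter on low values that of the 2-cell-like list was 0.30.

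Ribosomal protein genes, which code for the structural proteins of the ribosome, were lower as a list (median -0.32, 83 genes, adjusted p = 4.3e-11, camera in limma, and adjusted p = 0.732 with an estimated correlation). Part of this size went with transcript length, since the median was -0.12 with the length trend removed and lists matched on length and level had -0.13. After quantile normalization it was -0.19. Rpl36 had -1.07, Rps27 -1.02, Rpl12 -0.74 and Rps12 -0.72. Genes of the integrated stress response, which is switched on by amino acid shortage and by misfolded proteins, were lower too (median -0.41, 24 genes, adjusted p = 2.6e-06, and adjusted p = 0.630 with an estimated correlation). Besides Ddit3 and Nupr1, the chaperone gene Hspa5 had -0.84 and the pseudokinase gene Trib3 -0.79, and Nupr1 alone was lower adjusted over the list alone. Trophoblast genes had a median of -0.06 over 13 genes, with -0.11 and -0.08 in the separate hairpins (adjusted p = 0.0117, and adjusted p = 0.732 with an estimated correlation). That median was -0.22 after quantile normalization and -0.10 among genes with a mean FPKM of at least 1. Of its members 6 were below the control in both hairpins. The largest changes were those of the epithelial keratin genes Krt7 (-0.99), Krt18 (-0.72) and Krt8 (-0.38) and of Plac1 (0.80). Krt7 alone was lower adjusted over the list alone. When either NeuP replicate was left out, which leaves the NeuP group with 1 library, camera called 4 lists, endoderm (adjusted p = 0.0290 and 0.0291), 2-cell-like (0.0312 and 0.0311), the stress response and ribosomal protein genes.

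The other 14 lists were not called in the knockdown by camera in limma, and 0 of their members passed the threshold across all genes. Neural progenitor genes, which mark the cells of the NeuP libraries, had a median of 0.15 (30 genes, adjusted p = 0.442). Within them the Notch ligand Dll1 had -1.31, Fabp7 0.71 from hairpin values of 0.00 and 1.41, Meis2 0.58 and Gli3 0.57. With voom the neural progenitor list was called (median 0.72, adjusted p = 0.0133), as it was with a pseudocount of 0.1. Neuron genes had a median of 0.25 (12 genes, adjusted p = 0.847), with 1.04 for Neurod1, 1.02 for Gap43 and -0.61 for Elavl3. HOX genes had a median of 0.12 (12 genes, adjusted p = 0.372), with 0.49 for Hoxc13 and 0.34 for Hoxb9. Imprinted genes had a median of 0.32 (14 genes, adjusted p = 0.372), led by Peg3, the growth factor gene Igf2 (0.82), Grb10 (0.69) and Mirg (0.61), and Peg3 was higher adjusted over the list alone. Other nucleoporins had a median of 0.11 (29 genes, adjusted p = 0.847), with 0.79 for Pom121, 0.69 for Nupl2 and 0.44 for Ranbp2.

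Collagen and other transcripts of feeder fibroblasts, on which the ESC were grown, had a median of 0.07 (26 genes, adjusted p = 0.951, camera in limma), with 0.82 for Col1a2, 0.81 for Col1a1 and -0.51 for Cyr61. Interferon response genes had a median of 0.11 (18 genes, adjusted p = 0.847), with 0.60 for the RNA sensor gene Ddx58 and -0.50 for B2m. Camera compares a list with all other genes, and the median change over all genes was 0.08. A direction of down can therefore stand beside a small median above 0. For glia and proliferation, whose medians were not below 0.08, the cause was not tested. In all, camera gave a direction of down beside a median above 0 for a further 6 lists. These were glia (median 0.10, 11 genes, adjusted p = 0.791, Pdgfra 0.64), PRC1 subunits (0.05, 20 genes, 0.783, Pcgf6 0.51 and Cbx8 -0.48), PRC2 subunits (0.04, 11 genes, 0.605, Phf1 0.32 and Ezh2 -0.28), p53 targets (0.07, 27 genes, 0.951, Btg2 0.60 and Pmaip1 -0.48), proliferation (0.11, 39 genes, 0.390, Mki67 0.91) and replication-dependent histones (0.00, 7 genes, 0.840, Hist1h2bc 0.65). The mesoderm list had a median of 0.02 and a mean of -0.13 (8 genes, adjusted p = 0.372), because its largest change was -1.34 in the blood regulator Gata2 beside 0.42 in Eomes. The mesoderm median turned sign between the hairpins, with 0.19 in #2 and -0.16 in #4, as did that of p53 targets (0.13 and -0.04). Medians in the same order were 0.03 and 0.16 for glia, 0.00 and 0.05 for PRC2, 0.18 and 0.04 for interferon response, 0.20 and 0.11 for HOX, and -0.10 and -0.17 for histones. Single genes also differed between the hairpins, with 0.76 and 0.37 for Gli3, 0.94 and 0.44 for Grb10, and 0.90 and 0.41 for Hist1h2bc. Camera called mesoderm without hairpin #2 (adjusted p = 0.00533), HOX without hairpin #4 (0.00224) and histones without a filter on low values (0.00353).

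**Figure D2:**
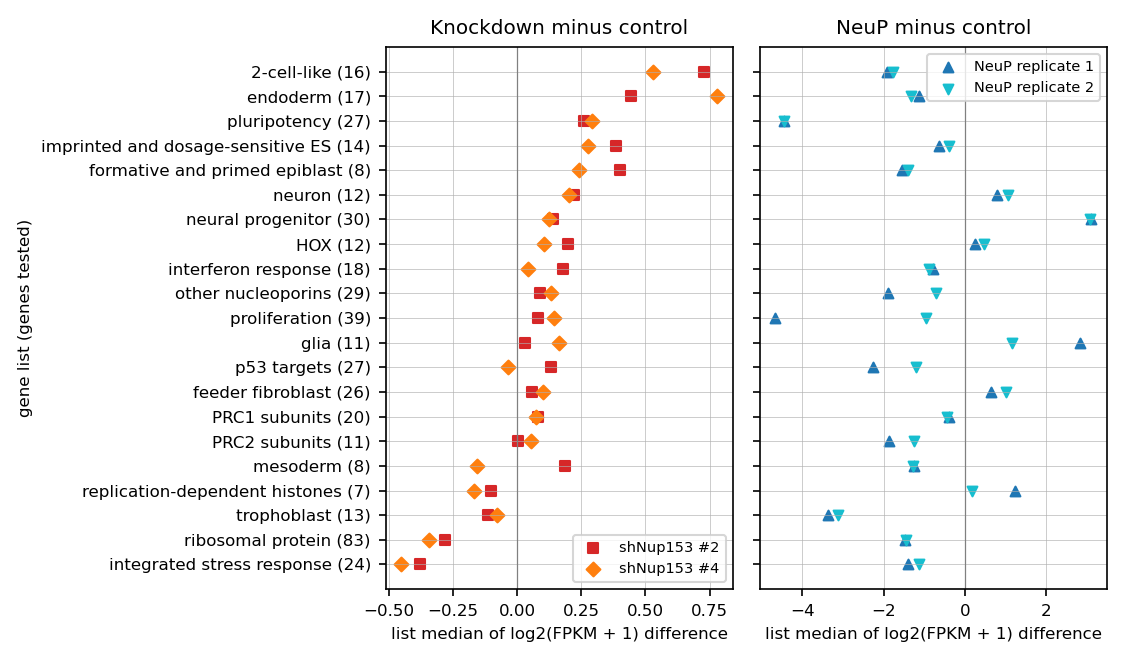
Median log2 change of each of 21 gene lists for each hairpin minus the control and each NeuP replicate minus the control, 1 point per library. The 2-cell-like list lay above 0 in both hairpins (median 0.66 in the fit) and below 0 in both NeuP replicates (-1.91).

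The second comparison asked how the neural progenitors differ from control ESC. The labels give no line for NeuP, so a difference between lines would enter every value of this comparison. Fabp7, a fatty acid binding protein of radial glia, was listed at 0 FPKM in the control and at 2799 ± 488 (SD, n = 2) in NeuP, a log2 change of 11.44 ± 0.68 (SE, adjusted p = 0.00289, limma, Benjamini-Hochberg). The other genes with the largest rises were the growth factor gene Ptn by 8.66 ± 0.29, its receptor gene Ptprz1 by 8.27 ± 0.29, the transcription factor genes Olig2 by 7.84 ± 0.27 and Olig1 by 7.61 ± 0.50, and the membrane glycoprotein genes Gpm6b by 8.45 ± 0.29 and Gpm6a by 7.44 ± 0.26. The leucine-rich repeat gene Lrrn1 rose by 7.83, the matrix gene Sparcl1 by 7.72 and the neuropeptide receptor gene Adcyap1r1 by 7.72. Among these 10 genes the largest adjusted p was 0.0108, for Sparcl1.

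Pluripotency factors fell. Pou5f1, which codes for Oct4, went from 543 FPKM to 1.82 ± 0.236 and Nanog from 246 FPKM to 0.701 ± 0.239, log2 changes of -7.59 ± 0.21 and -7.19 ± 0.24. Dppa5a went from 432 to 0.171 FPKM, the Oct4 target Fbxo15 from 248 to 0.230, the fatty acid binding protein gene Fabp3 from 454 to 0.0815 and the epithelial cadherin gene Cdh1 to 0.0635 (log2 change -7.57). The germline gene Dazl (-7.44), the tumour antigen gene Trap1a (-7.49), the protease inhibitor gene Wfdc2 (-7.33) and the mitochondrial gene Chchd10 (-7.25) fell as well. All 10 had an adjusted p of 0.00238 (limma, Benjamini-Hochberg). Nup153 had a log2 change of -0.99 and did not pass (adjusted p = 0.218), with -1.55 in NeuP replicate 1 and -0.42 in replicate 2.

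Limma called 2516 genes higher and 3420 lower in NeuP of 13750 tested, and voom on the recovered reads called 2610 and 3271. The counts depended on single libraries, since each arm lends its spread to the fit. Without hairpin #2 they were 319 and 1508, without hairpin #4 318 and 1504, without NeuP replicate 1 4692 and 5927, and without NeuP replicate 2 4616 and 6629. Quantile normalization moved the median change over all genes from -0.26 to -0.06 and gave 2900 higher and 2865 lower.

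Of the 21 lists, 11 were called in NeuP by camera with its preset correlation and 0 with an estimated one. Fry called 11 too, but not the same ones. It did not call glia (adjusted p = 0.0685), PRC2 subunits (0.0650) or other nucleoporins (0.196), and it called the formative (0.0105), neuron (0.0156) and interferon response (0.0145) lists, which camera did not. In the neural progenitor list, 24 of 30 genes rose and 0 fell (median 3.13, adjusted p = 5.3e-12, camera in limma, and adjusted p = 0.491 with an estimated correlation), and 28 were higher adjusted over the list alone. In the glia list 4 of 11 rose and 2 fell (median 2.00, adjusted p = 0.0342, and adjusted p = 0.557 with an estimated correlation). The astrocyte genes Slc1a3 (6.45), Aldoc (4.83), Aqp4 (4.77) and S100b (4.37) rose, while the myelin gene Mbp and the astrocyte gene Aldh1l1 fell, the last pair named after their values were seen. The glia median was 2.83 in NeuP replicate 1 and 1.16 in replicate 2, and the list was not called without hairpin #2 or #4 (adjusted p = 0.0524 for each) or after quantile normalization (0.0617). In the pluripotency list 26 of 27 genes fell and 0 rose (median -4.45, adjusted p = 1.7e-11, and adjusted p = 0.491 with an estimated correlation). The exception was Sox2, also a neural factor and named after its values were seen, at 49.9 FPKM in the control and 97.1 ± 18.3 in NeuP (log2 change 0.93, adjusted p = 0.0564, limma), which was higher adjusted over the list alone.

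All 16 genes of the 2-cell-like list fell, with -2.62 for Usp17le (median -1.91, adjusted p = 2.4e-05, camera in limma, and adjusted p = 0.557 with an estimated correlation). Among ribosomal protein genes 50 of 83 fell and 0 rose (median -1.47, adjusted p = 1.4e-08, and adjusted p = 0.491 with an estimated correlation), with the largest falls in the tissue-restricted paralogs Rps4l (-6.49), Rpl39l (-6.26) and Rpl10l (-4.47), followed by Rpl36. Among trophoblast genes 10 of 13 fell and 1, Tfap2a, rose (median -3.25, adjusted p = 0.00168, and adjusted p = 0.491 with an estimated correlation), led by the epithelial keratin genes Krt18 (-6.24) and Krt8 (-4.68) and the trophoblast regulator gene Tfap2c (-4.57). Among p53 targets 15 of 27 fell and 0 rose (median -1.70, adjusted p = 0.00117, and adjusted p = 0.557 with an estimated correlation), with -5.42 for the desmosome gene Perp and -5.21 for the apoptosis gene Pmaip1. In the integrated stress response list 12 of 24 fell and 1, Vldlr, rose (median -1.12, adjusted p = 0.0342, and adjusted p = 0.491 with an estimated correlation), with -4.57 for Ddit3, -4.01 for Trib3 and -3.10 for the asparagine synthetase gene Asns. Without hairpin #2 or #4 the stress response list was not called (adjusted p = 0.0658 and 0.0657).

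Endoderm genes fell in 9 of 17 and rose in 1, the chemokine receptor gene Cxcr4 (median -1.23, adjusted p = 0.0269, camera in limma, and adjusted p = 0.653 with an estimated correlation), and the members that fell most code for basement membrane, Lama1 (-5.28), Col4a2 (-3.59) and Col4a1 (-3.43). Other nucleoporins fell in 7 of 29 (median -1.40, adjusted p = 0.0311, and adjusted p = 0.774 with an estimated correlation), with -2.66 for Nup62, -2.19 for Nup93, -2.17 for Nup188 and -1.83 for Rae1. Their median was -1.91 in NeuP replicate 1 and -0.72 in replicate 2, and without hairpin #2 or #4 the list was not called (adjusted p = 0.0622 and 0.0623). PRC2 subunits fell in 4 of 11 (median -1.48, adjusted p = 0.0317, and adjusted p = 0.557 with an estimated correlation), namely Mtf2 (-2.82), Phf19 (-2.36), Suz12 (-1.92) and Jarid2 (-1.40), and the list was not called without hairpin #2 or #4 (0.0617 and 0.0616). Endoderm was not called without NeuP replicate 2 (0.181). The PRC1 list was not called (median -0.55 with a camera direction of up, 4 higher and 6 lower of 20, adjusted p = 0.872). In it Cbx7, the subunit profiled by ChIP, fell by 3.73, L3mbtl2 (-1.91) and Phc1 (-1.82) fell too, and Bmi1 rose by 2.78.

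The remaining lists were not called in NeuP by camera in limma. Neuron genes rose in 4 of 12 and fell in 1 (median 0.86, adjusted p = 0.0769), with 6.78 for Map2, 2.96 for Dcx, 2.80 for Gap43 and -5.55 for Stmn2. HOX genes split into 5 higher and 5 lower of 12 (median 0.37, adjusted p = 0.410). The anterior genes Hoxa2 (4.20), Hoxa3 (2.26) and Hoxa5 (1.70) rose and the posterior gene Hoxc13 fell (-2.20). Formative genes fell in 5 of 8 (median -1.48, adjusted p = 0.216), with -3.33 for Nodal and -2.77 for Otx2, while the neural factor gene Sox3 rose by 4.04. Mesoderm genes fell in 6 of 8 (median -1.26, adjusted p = 0.161), with -2.73 for Gata2. Imprinted genes rose in 3 and fell in 5 of 14 (median -0.49, adjusted p = 0.410), with -6.58 for Meg3, -6.09 for Rian, -5.12 for H19 and 5.28 for Nnat. Feeder fibroblast genes rose in 9 and fell in 6 of 26 (median 1.07, adjusted p = 0.135), with 5.07 for Col3a1, 4.12 for S100a4, -4.29 for Tagln and -4.24 for Ctgf. Interferon response genes fell in 9 and rose in 1 of 18 (median -0.82, adjusted p = 0.0769), with -4.95 for Ifitm1. Histone genes rose in 2 and fell in 1 of 7 (median 1.23, adjusted p = 0.252), with 3.25 for Hist1h2bc, 1.42 for Hist2h2be and -1.44 for Hist1h1a. Proliferation genes had a median of -2.82 (39 genes, 1 higher and 1 lower, adjusted p = 0.0996), the cyclin gene Ccnd3 being lower and the cell cycle inhibitor gene Cdkn1b higher (1.30). The replicates differed in this list, with a median of -4.67 in replicate 1 and -0.96 in replicate 2, and with either one left out the list was called (adjusted p = 0.0313 without replicate 1, 3.0e-08 without replicate 2), as it was after quantile normalization (0.0346) and with voom (0.0401). The proliferation marker Mki67 was measured at 1.18 FPKM in NeuP replicate 1 and at 80.2 FPKM in replicate 2, and the labels do not say whether the pair was taken at the same stage. Histone genes had a median of 0.18 without NeuP replicate 1. Without replicate 2, neuron genes (adjusted p = 0.0146) and feeder fibroblast genes (0.0476, median 0.65) were called, and without hairpin #2 or #4 mesoderm genes were called (0.0357 and 0.0422), as they were without a filter on low values (0.0125, median -0.13).

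The third comparison asked whether the knockdown moves ESC genes towards the NeuP pattern. Of the 22 genes at least 2-fold lower in both hairpins, 14 were also lower in NeuP by the same rule and 0 were higher. The 14 hold Ddit3, Nupr1, Myl3, Cox6a2, Crb3 and Krt17. Of the 42 genes at least 2-fold higher in both hairpins, 13 were also higher in NeuP, with Peg3, Ppp1r10 and Pros1 among them, and 10 were lower in NeuP, with Nodal, Gdf3, Zscan4d and Mpv17l among them. If the lists were independent, 4.92 of the lower genes would be lower and 3.48 higher in NeuP, and 6.65 of the higher genes would be higher and 9.39 lower, values that leave out the effect of the shared control. Lefty1, highest in the knockdown, was listed at 0 FPKM in both NeuP libraries. Across genes the r between the changes was 0.283 with a covariance of 0.155. Unchanged libraries sharing the control gave a simulated r of 0.242 and a covariance of 0.0166. The simulated NeuP libraries held no change of their own, unlike the real ones, so the 2 values of r cannot be set against each other. With no library shared the r was 0.103 and 0.111. The counts were also made with no library shared, setting 1 hairpin against the control and NeuP against the other hairpin, an alternative added after the data were seen. Of 37 genes 2-fold lower in hairpin #2, 12 (32.4%) were lower and 2 higher in NeuP, where independent lists would share 8.77 and 4.95. Of 74 in hairpin #4, 29 (39.2%) were lower and 3 higher, against 17.4 and 9.86. Of 78 genes 2-fold higher in hairpin #2, 11 (14.1%) were higher and 35 (44.9%) lower in NeuP, against 10.4 and 18.5. Of 115 in hairpin #4, 14 (12.2%) were higher and 38 (33.0%) lower, against 15.3 and 27.1. There NeuP is set against a knockdown library, so an effect common to both hairpins counts towards the opposite direction.

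The next comparisons asked where Nup153 contacts the genome and which factors bind there. The Nup153 DamID list held 3516 peaks over 10.4 Mb, of which 2336 were 2501 bp wide, the smallest width in the list. The widest peak, 15973 bp, lay in Esrrb, a nuclear receptor gene of naive pluripotency (chromosome 12, 87809875 to 87825847, 47.3 kb from the TSS). The next widest, at 8875 bp, lay on chromosome 5 (110893429 to 110902303) outside any gene with Fbrsl1 nearest. Others were over Odf3 and Scgb1c1 on chromosome 7 (148025994 to 148034174), over the TSS region of the amino acid transporter gene Slc38a1 on chromosome 15 (96464746 to 96472765) and over Mir7671 on chromosome 11 (53571380 to 53579399). Of the Nup153 peaks 35.0% lay within 2 kb of a TSS, against 16.8% of Oct4 DamID peaks. For Ring1B the share was 16.1% in control ESC, 35.8% in hairpin #2, 18.1% in hairpin #4 and 16.4% in NeuP. It was 27.3% for Cbx7, and 11.1% and 9.89% for Oct4 ChIP in control and hairpin #2. Only Ring1B in hairpin #2, a list that stood apart from the other Ring1B lists, reached the share of Nup153. Oct4 DamID, of the same assay and the same median width of 2501 bp, had a lower share. The ChIP lists differ from these in peak width, for which the shares were not adjusted. Nup153 peaks lay at the TSS of 1419 of 24016 genes (5.91%). They lay at 12 of 27 pluripotency genes, namely Pou5f1, Zfp42, Dppa3, Dppa5a, Fbxo15, Fgf4, Klf5, Mycn, Nr5a2, Sall4, Tbx3 and Tdgf1. They lay at 10 of 27 p53 targets, among them Cdkn1a, Bbc3, Fas and Pmaip1, at 6 of 22 endoderm genes, at 6 of 39 HOX genes, at 4 of 39 neural progenitor genes (En2, Meis2, Ncam1 and Nes) and at 4 of 84 ribosomal protein genes.

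By raw share Nup153 peaks overlapped most with Oct4 DamID and with Ring1B in control ESC, while by fold over shifted peaks Oct4 ChIP, which covers far less sequence, ranked above Ring1B. Oct4 DamID peaks overlapped 1457 of the 3516 Nup153 peaks (41.4%, 39.8 to 43.1), 48.7 times the mean of shifted peaks. Ring1B peaks overlapped 1406 (39.99%, 38.4 to 41.6, 24.0-fold) in control ESC, 1303 (37.1%, 35.5 to 38.7, 15.6-fold) in hairpin #2, 1008 (28.7%, 27.2 to 30.2, 16.9-fold) in hairpin #4 and 453 (12.9%, 11.8 to 14.03, 6.19-fold) in NeuP. Cbx7 peaks overlapped 495 (14.1%, 7.43-fold), and Oct4 ChIP peaks 219 in control ESC (6.23%, 34.1-fold) and 224 in hairpin #2 (6.37%, 32.1-fold). Each had an adjusted permutation p of 0.001, the smallest the 1000 shifts can give. Both DamID lists come from methylase fusions, which also methylate open chromatin, and the shifts do not keep distance to genes.

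Oct4 DamID was set against Oct4 ChIP to ask whether the methylase fusion finds the same sites. Both lists had a peak at Dppa3, Dppa5a, Fbxo15 and Mycn, while 3 pluripotency genes had one in the ChIP list only (Gdf3, Pou5f1 and Utf1) and 7 in the DamID list only (Dppa4, Klf5, Nr5a2, Sall4, Tbx3, Tdgf1 and Zfp42). Oct4 ChIP peaks in control ESC overlapped 376 of 3570 Oct4 DamID peaks (10.5%, 9.57 to 11.6), 57.1 times the mean of shifted peaks (permutation p = 0.001, the smallest possible). In the other direction DamID overlapped 390 of 1462 ChIP peaks (26.7%). The widest Oct4 DamID peak, 10538 bp, lay in Etl4 on chromosome 2 (20582199 to 20592736), followed by peaks near Btbd11 and Lpgat1 and in Arid5b and Rbpms. The ChIP lists had a fixed width of 177 bp in control and 175 bp in hairpin #2, and their headers gave 0.17% and 0.18% of tags in peaks.

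The comparison of Oct4 ChIP in control and hairpin #2 ESC asked whether Oct4 binding changes without Nup153. Oct4 peaks lay at the TSS of 7 of 27 pluripotency genes in control ESC (Dppa3, Dppa5a, Fbxo15, Gdf3, Mycn, Pou5f1 and Utf1) and at 8 in hairpin #2, the same genes and Tdgf1. Of 1462 control peaks 940 were found in hairpin #2 (64.3%, 61.8 to 66.7), and of 1598 hairpin #2 peaks 58.8% (56.4 to 61.2) were found in the control. Among control Oct4 peaks 67.9% overlapped Ring1B in control ESC, 35.4% Cbx7 and 7.80% Ring1B in NeuP. With 1 list per condition no spread between replicates of Oct4 was available to set these shares against.

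**Figure D3:**
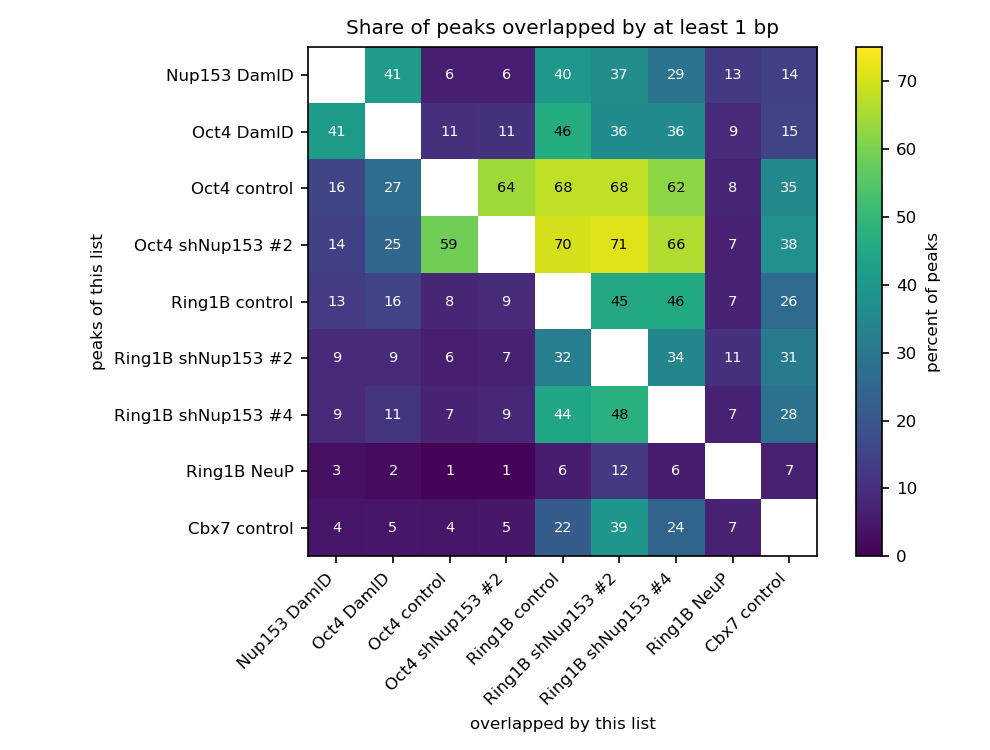
Share of the peaks of each list (vertical) that share at least 1 bp with each other list (horizontal), in percent, for the 9 peak lists. Oct4 peaks in control ESC overlapped Ring1B in control ESC at 67.9%, whereas Ring1B peaks in control ESC overlapped Ring1B in NeuP at 7.43%.

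Cbx7 was set against Ring1B in control ESC because both are PRC1 subunits. Cbx7 peaks lay at the TSS of 38 of 39 HOX genes, 34 of 39 neural progenitor genes and 22 of 25 mesoderm genes, and Ring1B peaks at 25, 24 and 13 of them. Both lay at the TSS of neural regulators such as Pax6, Olig2 and Sox1. The widest Cbx7 peak, 36505 bp, spanned Hoxa3 to Hoxa10 on chromosome 6 (52154624 to 52191128), followed by the Hoxb5 to Hoxb8 region and by peaks at the homeobox genes Pax2, Nkx2-1 and Uncx. The widest Ring1B peaks in control ESC lay at Tfap2a (7434 bp), Pax9, Hoxa10, Foxa1 and Sim1. Ring1B overlapped 2767 of 12454 Cbx7 peaks (22.2%, 21.5 to 23.0), 26.6 times the mean of shifted peaks (permutation p = 0.001, the smallest possible), and Cbx7 overlapped 26.1% of Ring1B peaks. The Cbx7 library held 22.5 M tags and the Ring1B control library 4.99 M, so the lists differ in depth as well as in the subunit.

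Ring1B in control and knockdown ESC was compared to ask whether PRC1 leaves its sites without Nup153. At neural progenitor genes Ring1B peaks lay at the TSS of 24 of 39 genes in control ESC, 38 in hairpin #2 and 30 in hairpin #4, and at HOX genes of 25, 39 and 26 of 39. Over all 24016 genes the counts were 1945 (8.10%), 5755 (24.0%) and 2220 (9.24%). In both hairpins it was found again at 20 neural progenitor genes, such as Pax6, Olig2, Sox1 and Zic1, and at 20 HOX genes. The control peaks missing from both hairpin lists lay at the TSS of 0 neural progenitor, 0 HOX and 0 mesoderm genes, of 2 pluripotency genes, Tbx3 and Tcl1, and of 5 p53 targets, Aen, Ccng1, Cdkn1a, Eda2r and Trp73. Over all 24016 genes there were 618 such genes (2.57%). This count follows the control peaks, and such a gene can have another Ring1B peak at its TSS in a hairpin list. In hairpin #2 the widest peaks spanned Hoxb4 to Hoxb8 (58287 bp) and Hoxa3 to Hoxa10, followed by Hoxc10 and Hoxc11, Dlx1 and Dlx2, and Six3. In hairpin #4 they lay at Hoxa7 and Hoxa9 (8257 bp), Ebf2, Tlx3, Isl2 and Sim1.

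Of 11916 control Ring1B peaks, 5389 (45.2%, 44.3 to 46.1) were found in hairpin #2, 5425 (45.5%, 44.6 to 46.4) in hairpin #4, 33.0% in both and 5030 (42.2%, 41.3 to 43.1) in neither. Of hairpin #4 peaks 47.7% (46.8 to 48.6) were found in hairpin #2, 45.1 times the mean of shifted peaks, and 44.4% (43.6 to 45.3) in the control, 67.8 times that mean. Of hairpin #2 peaks 34.3% (33.6 to 35.1, 42.2-fold) were found in hairpin #4 and 32.2% (31.4 to 32.9, 40.4-fold) in the control. By share the hairpins thus overlapped each other slightly more than the control, whereas by fold hairpin #4 overlapped the control more, as the hairpin #2 list covers more sequence. Control peaks with a Cbx7 peak were found at 81.2% in hairpin #2 and 71.8% in hairpin #4, and 9.87% of these 3109 were in neither, against 53.6% of the 8807 without Cbx7. Control peaks with a Nup153 peak were missing from both hairpins at 33.0% (30.7 to 35.4, 1569 peaks), and those without at 43.6% (42.7 to 44.6, 10347 peaks). The covered length was 7.93 Mb in the control, 15.7 Mb in hairpin #2 and 8.16 Mb in hairpin #4, with 4.99, 30.8 and 9.95 M tags. With this span of depths the share missing does not measure a loss of binding.

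The 4 HOX clusters show the spread between lists. In the Hoxd cluster (chromosome 2, 74506367 to 74603199) Ring1B covered 7.97% in control ESC, 77.3% in hairpin #2, 14.2% in hairpin #4 and 7.82% in NeuP, and Cbx7 covered 74.2%. In the Hoxa cluster (chromosome 6, 52105366 to 52210874) the shares were 30.8%, 76.8%, 33.9% and 27.3%, with 77.7% for Cbx7. Hoxb (chromosome 11, 96055675 to 96229567) had 4.82%, 48.7%, 4.79%, 6.59% and 40.7%, and Hoxc (chromosome 15, 102751562 to 102867283) 8.06%, 74.9%, 8.68%, 8.19% and 66.1%. Hairpin #2 stood apart from the other Ring1B lists and near Cbx7 in each cluster. It was the deepest ESC list, but the NeuP list was deeper still (33.2 M tags), and whether the libraries differ in antibody or preparation was not tested. Nup153 DamID had 1 peak in each of Hoxa, Hoxb and Hoxd and 4 in Hoxc.

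**Figure D4:**
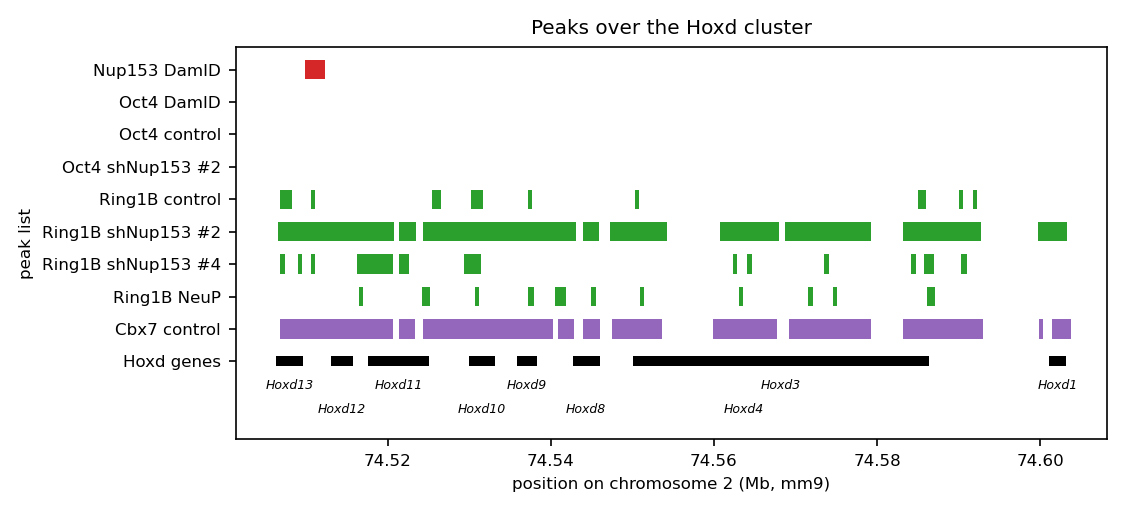
Peaks of the 9 lists over the Hoxd cluster on chromosome 2 (mm9 position), with the Hoxd genes drawn beneath, each bar being 1 peak. Ring1B covered 7.97% of the cluster in control ESC, 77.3% in hairpin #2 and 14.2% in hairpin #4, and Cbx7 covered 74.2%.

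Ring1B in ESC and NeuP was compared to ask how PRC1 sites differ between the cell types. At pluripotency genes Ring1B peaks lay at the TSS of 17 of 27 genes in control ESC, Pou5f1, Nanog and Esrrb among them, and of 2, Mycn and Sox2, in NeuP. At neural progenitor genes the counts were 24 and 18 of 39, and at HOX genes 25 and 21 of 39. The widest NeuP peak, 10090 bp, lay at Sim1 on chromosome 10 (50614525 to 50624614), which is also among the 5 widest in control ESC and in hairpin #4. The other wide ones lay at Igf2bp3, Otx2, 86.1 kb from Mir148a and at Hoxa9 and Hoxa10. Of 11916 control peaks 885 were found in NeuP (7.43%, 6.97 to 7.91, 9.07 times the mean of shifted peaks), and 5.98% of 14556 NeuP peaks were found in control ESC. The NeuP list was called against an IgG library from ESC, and with 1 list per cell type the spread between replicates is unknown.

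The last comparison asked whether genes with Nup153 or PRC1 at the TSS respond to the knockdown. The genes with an Oct4 ChIP peak had a median log2 change of 0.17 (151 genes), those with Nup153 0.10 (1225 genes), those with Ring1B 0.12 (1398 genes) and those with both Nup153 and Ring1B 0.14 (366 genes), against 0.08 for all other genes. Where the control Ring1B peak was found again in both hairpins the median was 0.13 (456 genes), and where it was in neither it was 0.11 (492 genes). These classes rest on overlap with the control peak. A gene of the latter class can still have another Ring1B peak at its TSS in the hairpin lists, as Dlk1 had in both. At least 2-fold higher in both hairpins were 4 genes with Oct4 (Gdf3, Lefty1, Nodal and Vegfc), 8 with Nup153 (L1td1, Nodal, Pkd2, Ppp1r10 and Pros1 among them), 9 with Ring1B, 3 with both (Krcc1, L1td1 and Nodal), 5 with Ring1B kept (Fam208a, Gdf3, L1td1, Nodal and Vegfc) and 3 with the control Ring1B peak in neither hairpin (Krcc1, Zc3h4 and C330021F23Rik). At least 2-fold lower in both hairpins were 1 gene with Nup153 (1190002F15Rik, also the only one with both), 2 with Ring1B (1190002F15Rik and Bhlhe41), 1 with Ring1B kept (Bhlhe41), and 0 with Oct4 or with the control Ring1B peak in neither hairpin. Over all genes the split of 42 higher and 22 lower became 23 and 45 after quantile normalization. Those of these genes outside the naming rule were chosen after their values were seen.

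Camera in limma called none of these classes, with adjusted p = 0.951 for Nup153, 0.765 for Ring1B, 0.949 for both, 0.951 for the control Ring1B peak in neither hairpin, 0.275 for Ring1B kept and 0.275 for Oct4. Fry, which does not compare with other genes, gave adjusted p = 0.0576, 0.0366, 0.0330, 0.261, 0.0330 and 0.0196 in the same order. Every fry call ended after quantile normalization (Ring1B 0.309, both 0.309, kept 0.437, Oct4 0.226). They ended as well with 1 kb around the TSS (0.0552 each), and those of Ring1B and of both ended among genes with a mean FPKM of at least 1 (0.0681 each) and with the length trend removed (0.0831 and 0.0597). With voom that of Ring1B ended (0.0515). The Nup153 class was called by fry with 5 kb around the TSS (0.0318), a pseudocount of 0.1 (0.0455) and without either NeuP replicate (0.0421), while Ring1B kept was not called without either NeuP replicate (0.0794). Without either hairpin the fry calls ended too, with 0.499 and 0.490 for Ring1B, for both and for Oct4, and 0.256 and 0.249 for Ring1B kept. Among random lists of matched expression the medians stood at percentiles 99.91, 100, 100, 98.99, 99.88 and 100, a ranking that treats genes as independent. After quantile normalization the medians were 0.03, 0.03, 0.08, 0.04, 0.03 and 0.10 in an order that ran Nup153, Ring1B, both, neither, kept and Oct4.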

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

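Over all alternatives, 3130 values were counted as the same, 161 became weaker, 22 became stronger, 66 moved and 0 reversed. For peak classes at the TSS a turn of direction with no call on either side counted as the same. Camera's direction for the Nup153 class, down in the main fit, was up with 1 kb around the TSS. It was also up after quantile normalization and with the length trend removed. The medians of mesoderm and p53 targets turned sign between the hairpins too, so directions did not hold throughout. Every one of 30 values for Nup153 DamID overlaps, 4 for Cbx7 with Ring1B and 3 for Oct4 DamID with Oct4 ChIP stayed the same. Among genes named in NeuP, 1112 values stayed the same, 109 became weaker and 1 became stronger, and among genes named in the knockdown 1314 stayed the same and 4 moved. No gene passed in the knockdown in the main fit, which could not call a 2-fold change, so staying the same there says little. Among list tests in the knockdown, 261 stayed the same, 28 became weaker and 5 became stronger, and in NeuP 258, 24 and 12. Where no reason is given the cause was not tested.

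Without a filter on low values, limma called 55 genes higher and 175 lower in the knockdown. With NeuP against all 3 ESC libraries, 5214 genes were lower. With 1 RNA library left out at a time, genes called in NeuP ran from 318 to 4692 higher and from 1504 to 6629 lower, lists called in the knockdown from 4 to 7 and lists called in NeuP from 8 to 13. A group left with 1 library was assumed to vary like the others.

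Genes 2-fold higher and lower in both hairpins numbered 388 and 65 with a pseudocount of 0.1, 1 and 4 with a pseudocount of 5, 615 and 171 at 1.5-fold, and 23 and 45 after quantile normalization, which sets the same median in every library. The r between hairpins was 0.787, 0.884, 0.844 and 0.847 with a pseudocount of 0.1, a pseudocount of 5, quantile normalization and the length trend removed. The r between knockdown and NeuP changes was 0.319, 0.267, 0.208 and 0.237 in the same order, and 0.103 and 0.111 with no library shared, where the shared control adds nothing. With no library shared, of genes lower in the knockdown 32.4% and 39.2% were lower in NeuP, and of genes higher in it 14.1% and 12.2% were higher and, for hairpin #2, 44.9% lower. Camera with an estimated correlation called 0 lists in the knockdown and 0 in NeuP, and fry called 0 in the knockdown and 11 in NeuP, of which the formative, neuron and interferon response lists were not called by camera. The estimated form had little power at 2 residual degrees of freedom. With voom and with the length trend removed camera called 6 lists in the knockdown. For genes with a peak at the TSS, fry called Ring1B (median 0.12), Nup153 with Ring1B (0.14), Ring1B kept in both hairpins (0.13) and Oct4 (0.17), as it does not compare with other genes. These calls ended after quantile normalization (adjusted p from 0.226 to 0.437), without either hairpin (0.249 to 0.499) and with 1 kb around the TSS (0.0552 each).

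With at least 50% of the peak covered, 60.47% of control Oct4 peaks were found in hairpin #2, and for control Ring1B peaks 42.6% in hairpin #2, 42.1% in hairpin #4, 29.6% in both, 44.96% in neither and 5.61% in NeuP. With up to 1 kb between peaks these Ring1B shares were 48.1%, 48.8%, 35.8%, 38.9% and 9.99%. In the wider 50% of each list they were 49.7%, 59.3%, 39.1%, 30.1% and 6.39%. With as many of the widest peaks as in the shortest list they were 42.8% in hairpin #2, 31.8% in both, 43.7% in neither and 6.62% in NeuP. Without 1 hairpin list the share in neither ran from 54.5% to 54.8%, since 1 list finds fewer. In the first 50% of the Oct4 lists in deposited order 67.99% were found.

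The length trend, voom, deposited order, leaving out a hairpin list, counts with no library shared and some further settings for lists and peak classes were chosen after seeing the data. Choosing Oct4 ChIP peaks by strength or width was not run, because they have a fixed width and no score, and deposited order took its place. A 2501 bp DamID peak cannot be covered by at least 50% by an Oct4 ChIP peak, so that setting gave no value there. Testing every transcript gave identical results, as each symbol occurs once. No paired analysis was possible because the DamID replicates were deposited as 1 list per factor, NeuP replicate numbers have no ESC counterpart and the hairpins are different sequences. The Ring1B control library, at 4.99 M tags, limits every share that starts from it.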

Other observations

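The genes with Nup153 at their TSS in ESC were lower in NeuP than other genes. Over 1225 such genes the median log2 change was -0.67, against -0.22 for all other genes, and 172 rose and 448 fell (camera adjusted p = 0.0145, limma, and adjusted p = 0.110 with an estimated correlation). The 366 genes with both Nup153 and Ring1B at the TSS had a median of -0.97, with 55 higher and 163 lower (adjusted p = 0.00683, and adjusted p = 0.110 with an estimated correlation). This class holds Pou5f1, Fbxo15, Dppa5a, Tdgf1, Sall4 and Nr5a2, which fell with the other pluripotency genes. Genes whose control Ring1B peak was in neither hairpin had a median of -0.65 (492 genes, 68 higher, 173 lower, adjusted p = 0.0429, and adjusted p = 0.322 with an estimated correlation). Such genes can still have another Ring1B peak at the TSS in a hairpin list. Genes that kept Ring1B in both hairpins, which hold Pax6, Olig2 and Hoxa2 but also Pou5f1, Fbxo15 and other pluripotency genes, had a median of -0.28 (456 genes, 116 higher, 151 lower, adjusted p = 0.932). Genes with Ring1B as a whole had -0.49 (adjusted p = 0.398) and genes with Oct4 -0.62 (adjusted p = 0.276). Fry, which does not compare with other genes, called every class lower (adjusted p from 7.2e-05 to 0.00350). Among random lists of matched expression, Nup153, Ring1B, both and neither stood at percentile 0, Oct4 at 0.53 and Ring1B kept at 28.88. This ranking treats genes as independent. By it a low median in NeuP was not particular to genes with Nup153. These tests in NeuP were chosen after the data were seen.

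The tests against a departure of the control library, turnover of peak calls and a few gene clusters were chosen only after the result was seen, and the other 3 were written before.

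Ribosomal protein genes were lower than the control in both hairpins (median -0.32, 83 genes). Their transcripts are short, with a median of 0.715 kb against 2.70 kb for all tested genes, and the change in each hairpin rose with length (Spearman 0.236 and 0.235 over genes, which are not independent). The list lay at percentile 0 of lists matched on length and level, whose median was -0.13 (-0.21 to -0.06), and with the length trend removed it was still called at -0.12 (adjusted p = 0.000113, limma, and adjusted p = 0.720 with an estimated correlation), which argues against length as the whole cause where genes are taken as nearly independent. The list median of hairpin #4 minus hairpin #2 was -0.0279, against -0.28 and -0.34 from the control, so a departure of the single control library and an effect of the knockdown cannot be told apart without a further control library. Levels of these genes are uncertain because many near-identical pseudogenes exist.

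Of control Ring1B peaks 42.2% were in neither hairpin list. The share of control peaks in hairpin #2 differed from the share of hairpin #4 peaks in hairpin #2 by -2.48 percentage points (45.2% and 47.7%). This gap, beyond the counting intervals, met the prediction for turnover of peak calls between libraries, but the test cannot decide. Its reference, hairpin #2, stood apart from the other Ring1B lists, and the libraries differ in depth. With hairpin #4 as the reference the shares were 45.5% of control peaks and 34.3% of hairpin #2 peaks. For loss of Ring1B at Nup153 sites the difference was -1.51 points among peaks wider than the most common width, with 18.1% (15.8 to 20.7) of 955 missing at Nup153 sites and 19.6% (18.4 to 20.9) of 4021 elsewhere. Because these intervals overlap, such a loss and its absence cannot be told apart, and a small loss at few sites might remain unseen. Width mattered more, as 58.6% of the 6940 peaks of that width or less were missing.

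Among genes with a mean level over 5 FPKM on the log scale, the 505 on chromosome 8 had a median log2 change of -0.85 in NeuP, lower than any other autosome (-0.55 on chromosome 12 to -0.07 on chromosome 14), and of 0.09 in the knockdown. Ring1B peaks in control ESC were 1.60 times as dense there as on the median autosome, little above chromosomes 6 (1.49) and 12 (1.39), whereas Ring1B peaks in NeuP were 0.569 times as dense, the lowest of the 19 autosomes with chromosome 12 next (0.766). An additional copy of chromosome 8 in the ESC fits, since 100% of 13 windows of 10 Mb had a NeuP to control peak ratio under the median (0.361 against 1.34). The RNA lay at -0.54 from the other autosomes, where 3 copies against 2 would give -0.58. These windows and this RNA value are from the data that showed the pattern, so they show its spread along the chromosome and are no separate support. The peak ratio lay further down than 3 copies against 2 would give in proportion. A few gene clusters were argued against, as 83.3% of the windows with enough genes, 10 of 12, lay under the other autosomes. No karyotype was given, NeuP and ESC may be of different lines, the NeuP peaks were called against an ESC IgG library, and beyond the copy number no biological explanation was tested.

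Xist, the RNA that silences an X chromosome, was measured at 16.4 and 113 FPKM in the NeuP replicates and at 0.0440, 0.0340 and 0.158 FPKM in the control, hairpin #2 and hairpin #4 ESC. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were at most 0.0180 FPKM in all 5 libraries.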
